A study of Caenorhabditis elegans with 4 samples.

How the data were processed

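Total RNA was sequenced from synchronized first-stage (L1) larvae of Caenorhabditis elegans with 2 genotypes, wild type (the N2 Bristol strain) and an lsm-8 mutant, homozygous per the labels, with 2 libraries of each. Per the labels' protocols, eggs hatched for 16 hours without food and non-green larvae of L1 size were sorted. The sorted larvae were then fed again for 2.5 hours before RNA was extracted. The mutant allele is kept over nT1[qIs51], a balancer made of a translocation between chromosomes IV and V that carries a green marker, so non-green larvae lack the marker. Per the labels' protocols the libraries were made with a stranded total RNA kit and read as single ends of 50 bases.

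The deposited table of raw counts holds whole-number read counts per gene, not normalized, for the 4 libraries. A second deposited table holds log2 values. Its scaling is not stated, and from the values each entry equals the log2 of the count times the mean library total over the library's own total, plus 8 (largest relative deviation 3.7e-14). The other deposited column, the width the authors gave each gene, was taken as the gene's length in bases. Bowtie, edgeR 3.24.0 and the genome build ce10 are named in the submitters' processing notes, without their roles. The counting tool, the gene annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart. Reads of near-identical gene copies, such as histone genes and hsp-16 genes, may have been split between them in a way that cannot be checked here.

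The table lists 20392 genes by WormBase identifier. Names and chromosomes were looked up by identifier in the reference tables and the WBcel235 annotation, which gave a name to 19182 genes and placed 19870. WBcel235 is not the build of the deposited tables, so it was used only for names, chromosomes, gene order and exon numbers, and no coordinate is given. Library totals ran from 50755251 to 101230177 counts. The mutant libraries were on average 1.83 times as deep as the wild-type libraries. A count of 0 allows up to 0.0551 and 0.0591 CPM (the share of a gene in the library total, scaled up) in the wild-type libraries and 0.0296 and 0.0331 CPM in the mutant libraries, at 3 counts, which covers counting error only.

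Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts (filterByExpr) and robust dispersion estimates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are mutant over wild type, and their standard errors were derived from the F statistic. CPM values use the TMM library sizes and are given as mean ± SD of 2 libraries. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and adjustment over the 35 lists with at least 5 tested members. The same test with an estimated correlation is given beside each called list. Enrichment of called genes by chromosome and exon number was tested with Fisher's exact test, two-sided, over the genes tested, and adjusted over the chromosomes and directions.

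The design, the tests, the classes of lists and the rule for named genes were fixed before the data were examined. The rule takes lsm-8, the other LSM genes, xrn-2, and unc-54 and myo-2, whose sequences are part of the marker in the mutant allele. It then takes the 10 largest rises and 10 largest falls among called genes with a locus name, a mean of at least 5 CPM and both mutant libraries beyond both wild-type libraries. The 3 largest of each under the same limits on level and overlap, with or without a locus name, are added. Last, it takes from each list the 2 called members with the largest rise and the 2 with the largest fall. It named 142 genes, and the text prints those that describe a list. For the 7 named genes with 3 or fewer counts in a library, no fold is given. Of the 685 gene symbols written out in the lists, 656 were found in the table, and 22 tested genes are in more than 1 list.

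The tests were checked on simulated counts of 16771 genes, drawn from their real means, the library sizes and the fitted trend of dispersion over expression. Of these genes, 67 were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Genes more variable than the trend are thus not represented, and far fewer genes were changed than the 4737 called in the data. The shares that follow may therefore differ from those in the data. Of the genes changed 1.5-fold, 61.2% were recovered, against 83.6% at 2-fold and 98.5% at 4-fold. Among genes above 5 CPM these shares were 92.5%, 100% and 100%. There were 9 calls of unchanged genes, 5.26% of the calls. Unchanged data gave 0 genes and 0 lists called. Simulated genes were drawn independently of each other, so this cannot show how often lists of correlated genes are called falsely. A planted shift of -0.30 in all ribosomal protein genes was called by camera with the preset correlation. With an estimated correlation camera gave it an adjusted p of 0.0858, so that setting missed a shift of this size in this simulated draw.

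Alternatives changed the normalization (DESeq2 size factors, upper quartile, library totals only), the filter (none, or at least 5 CPM in 2 libraries), the test (DESeq2 1.42.0, limma voom, limma on the deposited log2 values) and the model (the replicate number as a block). Others left out each library in turn, thinned all libraries to the smallest total, or removed the 20 most counted genes. For lists, the alternatives were camera with an estimated correlation, fry, DESeq2 size factors, the block and each library left out. A correction for gene length and a run without the genes of chromosome IV were added after the data were seen. Figures were drawn with matplotlib 3.10.9.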

Results

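The data are gene-level read counts of total RNA from sorted L1 larvae of 2 genotypes. The wild-type group had 2 libraries, with 54419838 and 50755251 counts, and the lsm-8 mutant group had 2 libraries, with 101230177 and 90749329 counts. LSM-8 is the subunit that sets the nuclear LSM2-8 ring, which binds U6 RNA, apart from the cytoplasmic LSM1-7 ring. The comparison asks which transcripts differ in lsm-8 mutant larvae, in a study of RNA decay by LSM2-8 and the nuclear exonuclease XRN-2 at genes marked by H3K27me3. No chromatin data were analysed here. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

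The targeted gene was lower in both mutant libraries. The transcript of lsm-8 (WBGene00003082, chromosome IV) stood at 15.4 and 15.9 CPM in the wild-type libraries and at 3.25 and 3.73 CPM in the mutant libraries. Its log2 fold change was -2.17 (SE 0.11, n = 2 and 2, edgeR adjusted p = 3.85e-11), which left 0.223 of the wild-type level. Whether these reads come from parts of the gene left in the allele, from heterozygous larvae passing the sort or from maternal RNA was not tested. None of the 7 other LSM genes was called, whether adjusted over all genes or adjusted over the list alone (0 of 7, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom). Among them, lsm-3 had a log2 fold change of 0.22 (SE 0.09, adjusted p = 0.0855) and lsm-4 of -0.25 (SE 0.10, adjusted p = 0.0758). Some alternatives called members of this list. The gene lsm-3 was higher without mutant replicate 2 (adjusted p = 0.00417), with upper quartile scaling (0.0471), library totals (0.0284), the deposited log2 values (0.0351) or, with lsm-6, a correction for gene length (0.0317 and 0.0359). In turn, lsm-4 was lower without wild type replicate 2 (0.00509) or mutant replicate 1 (0.00906). The exonuclease gene xrn-2 rose from 79.0 ± 5.73 to 107 ± 3.01 CPM (log2 fold change 0.44, SE 0.06, adjusted p = 2.58e-05). The mutant allele carries a red marker built from the myo-2 promoter and the unc-54 3' UTR. Counts of unc-54, a muscle myosin gene, rose by a log2 fold change of 0.31 (SE 0.06, adjusted p = 0.000822). Those of myo-2, a pharyngeal myosin gene, rose by 0.18 (SE 0.06, adjusted p = 0.0331), a call that was lost without any single library except mutant replicate 1, with the replicate block and with the correction for gene length (adjusted p up to 0.302 over all alternatives).

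Among called genes with a mean of at least 5 CPM, the largest rise was that of srw-85 (WBGene00005832, chromosome V), a predicted chemoreceptor gene, which stood at 0.789 and 0.959 CPM in the wild-type libraries and at 30.2 and 33.8 CPM in the mutant libraries, a 36.6-fold rise (log2 fold change 5.20, SE 0.13, adjusted p = 3.59e-15). It was followed by cpr-2, a cathepsin B-like protease gene, which rose 7.56-fold from 11.9 ± 2.31 CPM, and by clec-74, a C-type lectin gene, which rose 5.73-fold from 2.39 ± 0.297 CPM. Among genes of this level with a locus name, the next largest rises were those of dgat-2 (4.71-fold), a diacylglycerol acyltransferase gene, the trehalase gene tre-5 (4.36-fold) and the ABC transporter gene pgp-1 (4.04-fold). The glutathione S-transferase gene gst-38 rose 3.32-fold, the sodium-calcium exchanger gene ncx-7 rose 3.21-fold, the heme transporter gene hrg-4 rose 3.02-fold and rhy-1 rose 3.02-fold. Adjusted p-values of these 10 genes ran from 3.59e-15 for srw-85 to 0.00721 for pgp-1.

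Among called genes with a mean of at least 5 CPM, the largest falls with a locus name were those of 2 small heat shock protein genes on chromosome V. Levels of hsp-16.41 (WBGene00002018) fell from 46.6 ± 5.02 to 2.90 ± 0.414 CPM (log2 fold change -4.01, SE 0.11, adjusted p = 2.78e-14), and those of hsp-16.2 fell 12.2-fold, from 51.0 ± 2.64 CPM to 3.32 and 5.09 CPM in the mutant libraries. The acyl-CoA synthetase gene acs-2, which acts in fatty acid oxidation, fell 10.1-fold, from 103.6 ± 0.963 to 10.3 ± 4.30 CPM (adjusted p = 0.0336). The glyoxylate cycle gene icl-1 was abundant and fell 4.22-fold, from 3262 ± 76.7 to 773 ± 96.3 CPM (adjusted p = 2.99e-12). Asparagine synthetase asns-2 fell 4.18-fold (adjusted p = 1.61e-14), and falls of 3.98-fold to 4.24-fold were seen for dao-6, nceh-1, pud-4 and the collagen gene col-130. Among genes of this level without a locus name, Y58A7A.3 fell from 13.5 ± 1.32 to 0.759 ± 0.618 CPM (log2 fold change -4.18, SE 0.62, adjusted p = 0.0417). That call was lost with no filter and with the deposited log2 values (adjusted p up to 0.0655). Its fall rests on mutant libraries at 0.322 and 1.196 CPM, and the log2 fold change was -3.493 without mutant replicate 1 and -5.385 without mutant replicate 2.

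In all, 4737 of 16771 tested genes were called changed, 2258 higher and 2479 lower in the mutant, or 28.2% of the genes tested. Scaled by library totals only, 60.5% of 4827 calls were higher, against 47.7% of the 4737 calls with TMM. Most changes were small, with an absolute log2 fold change under 0.5 in 62.8% of calls and a median of 0.40. A change of at least 2-fold was found for 562 genes, 277 higher and 285 lower. That count was 186 when only genes of at least 5 CPM in 2 libraries were tested. The values of the groups did not overlap for 10530 tested genes, or for all 4737 called genes, where chance gives a share of 33.3% of tested genes for 2 against 2.

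**Figure D1:**
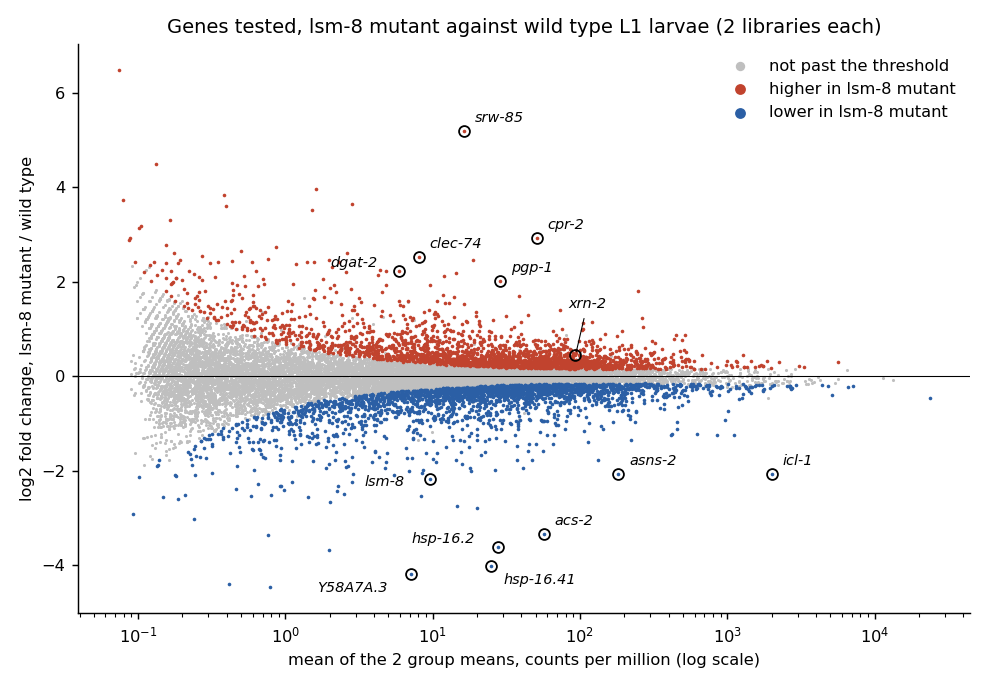
Each point is 1 of the 16771 tested genes, with the mean of both group means in CPM on a log axis (x) and the log2 fold change of lsm-8 mutant over wild type (y). Red and blue points are the 2258 higher and 2479 lower genes, and circles mark the genes labelled in the plot, from srw-85 at 5.20 to Y58A7A.3 at -4.18.

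Of the 35 gene lists tested, 14 were shifted as a whole by camera, 10 higher and 4 lower in the mutant. None of the 35 was called with an estimated correlation (smallest adjusted p = 0.423), where 2 had an unadjusted p under 0.05. The directional test of fry called 10 lists, and 9 were called by camera without wild type replicate 1 or without mutant replicate 2. Gene length and chromosome moved with genotype across all genes, and their values stand beside the lists concerned.

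Heat shock genes and targets of DAF-16 were shifted lower. In the list of heat shock and protein-folding stress genes, 17 of 28 members fell and 2 rose (21 called when adjusted over the list alone; camera adjusted p = 5.81e-05, adjusted p = 0.423 with an estimated correlation). Besides hsp-16.41 and hsp-16.2, the hsp-70 family gene F44E5.4 stood at 0.790 CPM in wild type and 0.0372 CPM in the mutant. The cochaperone gene dnj-13 rose by a log2 fold change of 0.47 (SE 0.06). Of 21 targets of the insulin pathway transcription factor DAF-16, 12 fell and 3 rose (16 adjusted over the list alone; camera adjusted p = 0.00233, adjusted p = 0.423 with an estimated correlation). Their median log2 fold change was -0.62. Members that fell include icl-1 and hsp-12.6 (-1.77, SE 0.33, from -1.28 to -2.48 over the alternatives), and members that rose include the insulin gene daf-28 (0.78, SE 0.11) and the fatty acid desaturase gene fat-5 (0.72, SE 0.13).

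Genes of fasting and lipid metabolism were shifted higher as a list, with 21 of 42 higher, 8 lower and 13 not called (34 adjusted over the list alone; camera adjusted p = 0.00945, adjusted p = 0.423 with an estimated correlation). The members moved in both directions. The desaturase gene fat-7 rose from 1.22 to 4.39 CPM (log2 fold change 1.84, SE 0.19) and the fatty acid elongase gene elo-5 from 57.02 to 98.0 CPM (0.78, SE 0.06). The fatty acid oxidation gene acs-2 (-3.34, SE 0.39) and the lysosomal lipase gene lipl-4 (-2.32, SE 0.28) fell. The list's call was lost without mutant replicate 2 (adjusted p = 0.0598).

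In the mitochondrial respiratory chain, 34 of 50 nuclear-encoded members fell and 0 rose (39 adjusted over the list alone; camera adjusted p = 3.81e-07, adjusted p = 0.634 with an estimated correlation). The falls were small, with a median log2 fold change of -0.22, and the largest were those of the complex I genes nduf-6 (-0.43, SE 0.07) and nduv-3 (-0.43, SE 0.09). Of 81 cytosolic ribosomal protein genes, 23 fell and 0 rose (27 adjusted over the list alone; camera adjusted p = 8.20e-05, adjusted p = 0.781 with an estimated correlation). Their median was -0.15, with rpl-14 at -0.35 (SE 0.06) and rps-24 at -0.32 (SE 0.06). Both lists hold short genes, with median lengths of 1067 and 638 bases. Across the 9621 genes with at least 5 CPM, the median log2 fold change went from -0.11 in the shortest 20% to 0.06 in the longest 20%. With a correction for gene length the ribosomal list had a median of -0.06 (middle 50% of members -0.10 to 0.02, against -0.20 to -0.10 before) and was not called (adjusted p = 0.107). The respiratory chain list had a median of -0.17 and was still called (adjusted p = 8.00e-06). The ribosomal call was also lost without mutant replicate 2 (adjusted p = 0.0773).

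Genes of C-type lectins and of the response to pathogens were shifted higher. Of 158 C-type lectin genes, 49 rose and 11 fell (64 adjusted over the list alone; camera adjusted p = 0.000105, adjusted p = 0.423 with an estimated correlation), with clec-74 up and clec-61 (-2.06, SE 0.17) and clec-5 (-1.67, SE 0.08) down. The genes clec-174 and clec-2 had 3 or fewer counts in each wild-type library and reached 0.712 and 0.303 CPM in the mutant. Among 35 pathogen-response genes, 15 rose and 4 fell (23 adjusted over the list alone; camera adjusted p = 0.00106, adjusted p = 0.423 with an estimated correlation). The gene irg-5 rose from 11.05 to 28.5 CPM (log2 fold change 1.37, SE 0.09) and hpo-6 from 25.8 to 63.1 CPM (1.29, SE 0.07). The antimicrobial saposin gene spp-1 fell from 78.4 to 40.5 CPM (-0.95, SE 0.08). Without genes of chromosome IV, which were higher along most of the chromosome, the pathogen-response list was not called (adjusted p = 0.172), with 18 of 35 members left and a median of 0.10 against 0.14.

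Markers of 5 somatic tissues were shifted higher. In body wall muscle 16 of 35 markers rose and 1 fell (18 adjusted over the list alone; camera adjusted p = 0.000553, adjusted p = 0.423 with an estimated correlation). The integrin-associated gene unc-112 (0.58, SE 0.06) and the acetylcholine receptor gene lev-1 (0.58, SE 0.08) rose, and the myosin chaperone gene unc-45 fell (-0.45, SE 0.06). In the intestine 13 of 31 markers rose and 4 fell (20 adjusted over the list alone; camera adjusted p = 0.0371, adjusted p = 0.423 with an estimated correlation). The intestinal GATA factor gene elt-2 rose from 6.17 to 18.1 CPM (log2 fold change 1.56, SE 0.10), and the ferritin gene ftn-1 (-1.34, SE 0.08) and the protease gene cpr-6 (-1.05, SE 0.06) fell. In the pharynx 7 of 19 rose and 1 fell (10 adjusted over the list alone; camera adjusted p = 0.0165, adjusted p = 0.423 with an estimated correlation), with peb-1 at 0.93 (SE 0.15) and phat-6 at -0.36 (SE 0.07). Neuron markers had 15 of 38 higher and 0 lower (15 adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.423 with an estimated correlation), among them the GABA transporter gene unc-47 (0.46, SE 0.09) and the acetylcholine transporter gene unc-17 (0.33, SE 0.06). Epidermis and seam markers had 9 of 23 higher and 1 lower (11 adjusted over the list alone; camera adjusted p = 0.0104, adjusted p = 0.634 with an estimated correlation), with rnt-1 at 0.43 (SE 0.13) and ajm-1 at -0.20 (SE 0.05). The call of rnt-1 was lost without wild type replicate 2 (adjusted p = 0.116) or mutant replicate 2 (0.0855), with the replicate block (0.05001) and with DESeq2 (0.0695), and that of ajm-1 without wild type replicate 2 (0.0537).

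Not all of these tissue calls held when a library was left out or genes were corrected for length. The intestine list was lost without each of the 4 libraries in turn (adjusted p from 0.0598 to 0.119), and the neuron list without wild type replicate 1, wild type replicate 2 or mutant replicate 2 (0.0777, 0.129 and 0.0933) and with the replicate number as a block (0.0538). The pharynx list was lost without wild type replicate 1 or mutant replicate 2 (0.101 and 0.0598), and the epidermis list without wild type replicate 1 (0.146). With the length correction, the intestine, neuron and epidermis lists were not called (adjusted p = 0.0761, 0.125 and 0.0751). The median moved little in the intestine list, from 0.13 (middle 50% of members -0.06 to 0.43) to 0.15 (-0.08 to 0.45), and in the neuron list, from 0.11 (-0.03 to 0.21) to 0.10 (-0.03 to 0.19). That of the epidermis list went from 0.17 (0.02 to 0.37) to 0.11 (0.02 to 0.37). Camera compares a list with other genes, and the median of all tested genes went from -0.007 to 0.014. Relative to all genes, the intestine median was nearly kept and the neuron and epidermis medians fell. An effect of length is thus not shown for the intestine list and stays open for the others. Without genes of chromosome IV the intestine and neuron lists were not called (0.103 and 0.112), with medians of 0.14 over 28 and 0.10 over 31 members. Body wall muscle was called in all of these settings.

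Regulators of developmental timing and of splicing were the remaining lists shifted higher. Of 20 heterochronic genes, which set the timing of larval cell fates, 12 rose and 1 fell (15 adjusted over the list alone; camera adjusted p = 0.00449, adjusted p = 0.673 with an estimated correlation). The period homolog lin-42 had a log2 fold change of 0.82 (SE 0.20) and the transcription factor gene hbl-1 of 0.67 (SE 0.08), while ain-2 fell (-0.19, SE 0.05). These are long genes, with a median of 3282 bases, and the list was not called with the length correction (adjusted p = 0.0601) or without wild type replicate 1 (0.0702). With the length correction its median went from 0.30 (middle 50% of members 0.12 to 0.42) to 0.24 (0.06 to 0.38), so most of the shift was kept. The call of lin-42 was lost without mutant replicate 1 (0.0503), and that of ain-2 without wild type replicate 1 (0.0789) or mutant replicate 2 (0.0577), with the block (0.0510), with library totals (0.0696) and with the deposited log2 values (0.07005). Of 51 spliceosome and splicing factor genes, 14 rose and 1 fell (15 adjusted over the list alone; camera adjusted p = 0.00646, adjusted p = 0.634 with an estimated correlation). The SR protein gene rsp-1 and the splicing regulator gene mec-8 each rose by 0.42 (SE 0.06 and 0.07), and the helicase gene mog-1 fell (-0.19, SE 0.06). The list's call was lost without wild type replicate 2 (0.113) or mutant replicate 1 (0.0560), and that of mog-1 without wild type replicate 1 (0.106) or mutant replicate 1 (0.0933), with the block (0.0576), with library totals (0.0756) and with the deposited log2 values (0.0785).

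Among lists that were not shifted, 12 of 35 RNA decay and surveillance factors rose and 1 fell (14 adjusted over the list alone; camera adjusted p = 0.0716). The nuclear exosome helicase gene mtr-4 rose with xrn-2 (log2 fold change 0.38, SE 0.06). Factors of H3K27 and H3K9 methylation had 4 of 24 higher and 7 lower (11 adjusted over the list alone; camera adjusted p = 0.354). The demethylase gene jmjd-3.1 rose (0.36, SE 0.06), and its paralog jmjd-3.2 fell from 14.5 to 7.80 CPM (-0.89, SE 0.09). Histone genes had 8 of 24 higher and 4 lower (12 adjusted over the list alone; camera adjusted p = 0.354), with a median of 0.16 and a mean of -0.01. Nuclear hormone receptor genes had 38 higher, 28 lower and 169 not called (66 adjusted over the list alone; camera adjusted p = 0.267), with nhr-85 rising from 11.6 to 27.9 CPM (1.27, SE 0.08) and nhr-38 falling from 1.39 to 0.134 CPM (-3.36, SE 0.34). Detoxification enzymes and transporters split into 40 of 202 higher and 51 lower (99 adjusted over the list alone; camera adjusted p = 0.698). Among them, ugt-15 fell from 3.69 to 0.289 CPM (-3.67, SE 0.23) and cyp-37B1 from 28.4 to 7.45 CPM (-1.93, SE 0.10). Of 7 splicing-stress and metal-responsive genes, the metallothionein gene mtl-1 fell (-1.36, SE 0.09) and no other was called (1 adjusted over the list alone; camera adjusted p = 0.102). Epidermal antimicrobial peptide genes had 3 of 18 higher and 6 lower (10 adjusted over the list alone; camera adjusted p = 0.303), with nlp-24 falling from 39.8 to 18.2 CPM (-1.12, SE 0.08). Of 32 pals genes, 8 fell and 0 rose (8 adjusted over the list alone; camera adjusted p = 0.199), among them pals-34 (-1.23, SE 0.24).

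Of 90 neuropeptide genes, 7 rose and 16 fell (23 adjusted over the list alone; camera adjusted p = 0.0848), with the insulin-like gene ins-20 up (2.42, SE 0.40) and ins-4 down (-1.64, SE 0.31). Without mutant replicate 1 this list was called lower (adjusted p = 0.0208). With the length correction 12 rose and 11 fell, and the median turned from -0.07 to 0.04 (adjusted p = 0.904). Homeobox genes had 14 of 87 higher and 3 lower (16 adjusted over the list alone; camera adjusted p = 0.162), with ceh-23 at 0.78 (SE 0.12) and ceh-88 at -0.81 (SE 0.09). Chemoreceptor genes were rarely called, with 30 of 787 higher and 24 lower (16 adjusted over the list alone; camera adjusted p = 0.667). Cuticle collagen genes had 19 of 136 higher and 12 lower (29 adjusted over the list alone; camera adjusted p = 0.700), with col-145 at -2.56 (SE 0.24). Moulting genes had 6 of 32 higher and 3 lower (9 adjusted over the list alone; camera adjusted p = 0.391), with let-653 at 0.70 (SE 0.11) and dpy-31 at -0.35 (SE 0.06). Hedgehog-related and patched-related genes had 10 of 79 higher and 4 lower (13 adjusted over the list alone; camera adjusted p = 0.303), with ptr-13 at -0.96 (SE 0.06). That list was called higher without wild type replicate 2 (adjusted p = 0.0440). DNA replication and cell cycle genes had 11 of 55 higher and 3 lower (13 adjusted over the list alone; camera adjusted p = 0.0848), with rfc-3 at 0.44 (SE 0.08) and rpa-2 at -0.40 (SE 0.06). Ribosome biogenesis and RNA polymerase I genes had 7 of 36 higher and 3 lower (10 adjusted over the list alone; camera adjusted p = 0.815), with fib-1 at -0.40 (SE 0.06).

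Germline markers had 3 of 35 higher and 3 lower (6 adjusted over the list alone; camera adjusted p = 0.698), with the Piwi gene prg-1 at 0.32 (SE 0.06). Oocyte and early embryo transcripts had 1 of 29 higher, spn-4, and 0 lower (0 adjusted over the list alone; camera adjusted p = 0.784). The call of spn-4 was lost without wild type replicate 2 (0.0846) or mutant replicate 1 (0.0823). Sperm genes had 3 of 26 higher and 2 lower (5 adjusted over the list alone; camera adjusted p = 0.911), with spe-4 falling from 3.34 to 0.970 CPM. Coelomocyte and excretory markers had 3 of 14 higher and 1 lower (4 adjusted over the list alone; camera adjusted p = 0.698). The list of LSM genes other than lsm-8 was not shifted (camera adjusted p = 0.954). Vitellogenin genes, with 3 tested, were too few for a list test, and vit-2 (1.32, SE 0.31) and vit-6 (0.86, SE 0.23) rose at levels up to 1.37 CPM, the latter not called by DESeq2 (adjusted p = 0.0546). The signs of the median, the mean and the camera direction were not all the same for histone, moulting, ribosome biogenesis, germline and cuticle collagen genes. The median of detoxification, moulting and ribosome biogenesis genes changed sign when libraries were scaled by upper quartile or totals. The length correction moved the median of all tested genes from -0.007 to 0.014. With this correction the list median changed sign for detoxification genes (-0.03 to 0.02), neuropeptides, epidermal antimicrobial peptides (-0.15 to 0.03) and LSM genes (-0.06 to 0.03). Without genes of chromosome IV it changed sign for histones, oocyte and early embryo transcripts (0.07 to -0.05) and coelomocyte and excretory markers (0.05 to -0.02).

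**Figure D2:**
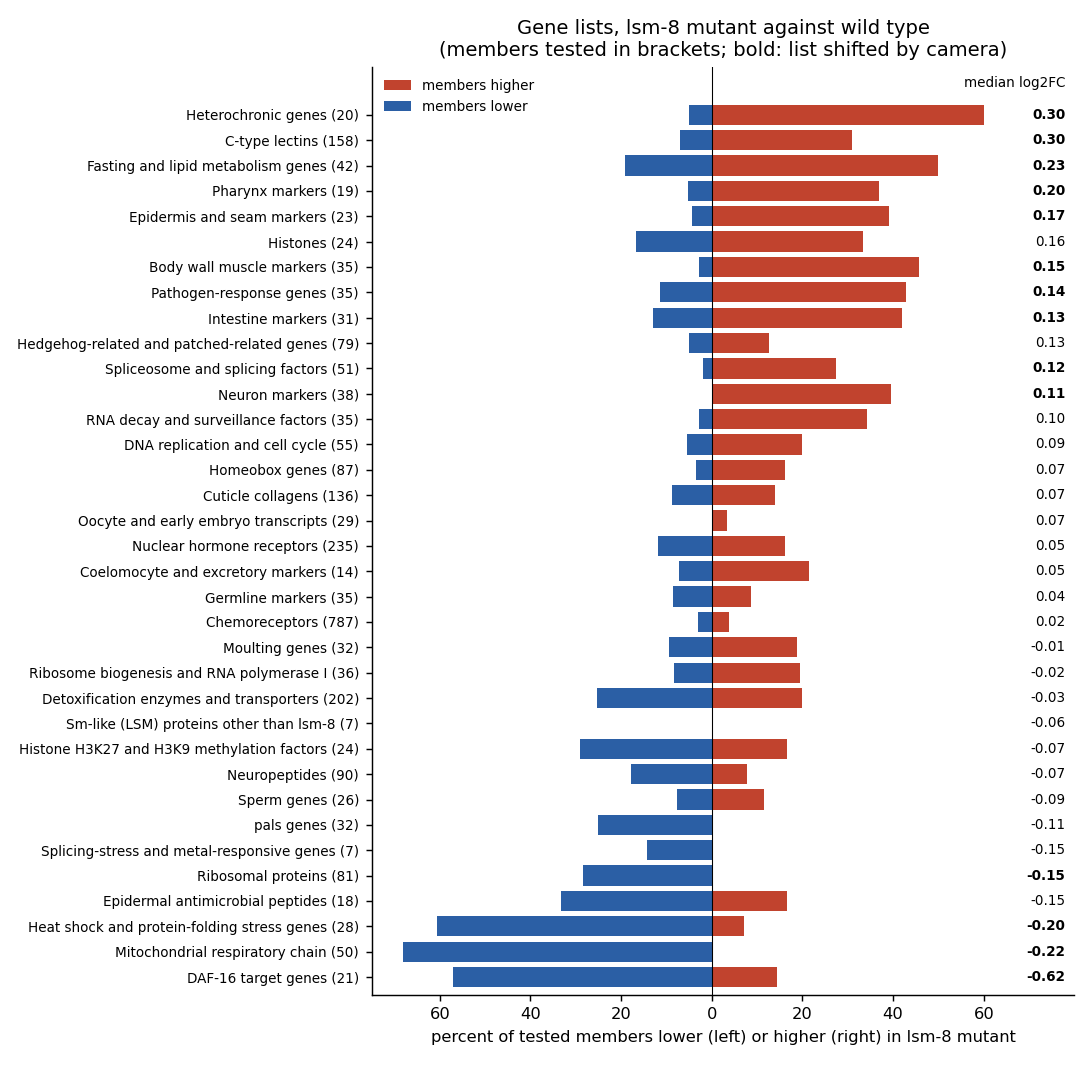
For each of the 35 lists (members tested in brackets), bars give the percent of tested members called higher (red, right) or lower (blue, left) in the lsm-8 mutant, and the figure at the right gives the list's median log2 fold change. The 14 lists shifted by camera are in bold, with medians from 0.30 for heterochronic genes to -0.62 for DAF-16 targets.

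Called genes were not spread evenly over the chromosomes. On chromosome IV, which holds lsm-8, 580 of 2658 tested genes rose (21.8%, against 11.8% elsewhere; odds ratio 2.09, Fisher's exact test adjusted p = 3.15e-38) and 241 fell (9.07%, against 16.15%; odds ratio 0.518, adjusted p = 5.25e-22). Among genes of at least 5 CPM, the median log2 fold change was 0.09 on chromosome IV (1535 genes), against -0.05, -0.04 and -0.05 on chromosomes I, II and III and close to 0 on V and X. The shift ran along most of the chromosome. Of 15 blocks of about 100 neighbouring genes, 13 had a median above 0, and the exceptions were the first block, from frm-5.1 to csn-4 (-0.09), and the last, from oig-5 to rabr-2 (-0.01). On chromosomes I to III, 9 of 47 blocks had a median above 0. Rises of at least 2-fold were also more frequent on chromosome IV, at 2.71% of tested genes against 1.43% elsewhere (odds ratio 1.91, Fisher's exact test adjusted p = 1.97e-05). Falls of at least 2-fold were less frequent there, at 0.715% against 1.91% (odds ratio 0.369, adjusted p = 7.44e-06). Of the genes tested on chromosome V, 3.05% were at least 2-fold higher (1.21% elsewhere; odds ratio 2.56, adjusted p = 2.20e-12) and 3.26% at least 2-fold lower (1.25% elsewhere; odds ratio 2.65, adjusted p = 1.55e-13). Its first block (ife-3 to fpn-1.2, median 0.18) and last 2 blocks (ZK218.1 to pbo-5, 0.16 and 0.20) were the highest on that chromosome. Of 12 mitochondrial genome genes, 6 fell and 0 rose (odds ratio for lower 5.68, Fisher's exact test adjusted p = 0.00810). All of these tests by chromosome count genes as independent, so their p-values do not measure the spread between libraries. Mitochondrial genome genes held 5.51% and 4.74% of counts in the wild-type libraries and 3.94% and 4.42% in the mutant libraries. Wild type replicate 2 and mutant replicate 2 thus lay closer together than the 2 wild-type libraries.

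**Figure D3:**
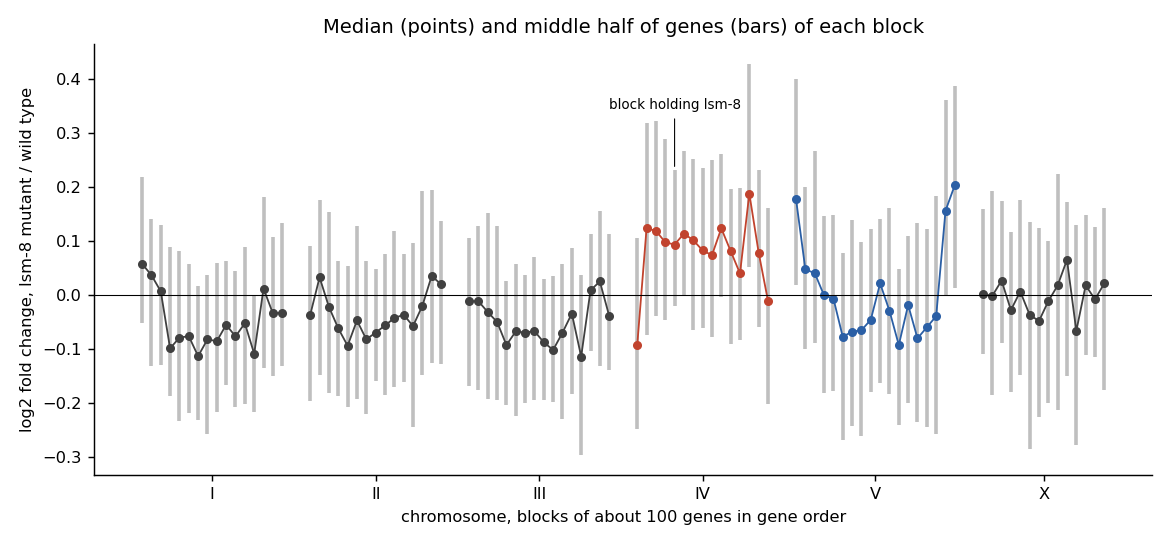
Points are the median log2 fold change (lsm-8 mutant over wild type) of blocks of about 100 neighbouring genes of at least 5 CPM, in gene order along each chromosome, and grey bars span the middle 50% of genes. Blocks of chromosome IV (red) lie above 0 except the first and the last, and the ends of chromosome V (blue) rise to 0.18 and 0.20.

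With the main settings, calls of single-exon and multi-exon genes did not differ past the threshold. Of 223 single-exon protein-coding genes, 22 rose (9.87%, against 13.7% of multi-exon genes; odds ratio 0.692, 95% interval 0.423 to 1.08, Fisher's exact p = 0.115) and 31 fell (13.9%, against 15.2%; odds ratio 0.899, 0.593 to 1.32, p = 0.639). Higher calls were less frequent among single-exon genes with upper quartile scaling (odds ratio 0.593, Fisher's exact p = 0.0168), library totals (0.559, p = 0.00588), no filter (0.435, p = 2.10e-05) and the deposited log2 values (0.617, p = 0.0207), as were lower calls with no filter (0.509, p = 8.28e-05). Calls were more frequent at higher expression, from 3.98% of genes higher and 3.32% lower in the lowest 25% of genes by mean CPM to 21.7% and 23.01% in the highest 25%. Changes of at least 2-fold went the other way, with 148 genes higher and 103 lower in the lowest 25% and 8 and 26 in the highest 25%.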

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

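The length correction, the run without chromosome IV, and the use of all gene-test alternatives for chromosome and exon results were chosen after the data were seen. The count of changed genes, 4737, stayed within 1.5 times under each alternative run (3655 to 4827), as did those of higher (1767 to 2920) and lower genes (1879 to 2541), and no called gene shared with the 4737 turned direction. Leaving out each library gave 3801 to 4380 changed genes and 499 to 614 changed at least 2-fold, where the lone library is assumed to vary like the other group. The count of at least 2-fold changes was 186 with the filter at 5 CPM, which tests fewer genes, and 417 with DESeq2. No scaling moved the median of all genes by over 0.1 (at most 0.05, by library totals). With 2 pairs, the samples share only a number (the deviations of same-numbered libraries correlated at -0.06 across genes), and the model with the replicate number as a block gave 3655 changed genes and 13 lists, without that of neuron markers. Lists shifted numbered 14, against 0 with an estimated correlation, 10 with fry, 14 with DESeq2 size factors, 10 with the length correction and 11 without chromosome IV. Without each library in turn they numbered 9 to 13. Fry did not call the respiratory chain, ribosomal, splicing, heterochronic and epidermis lists and called the pals list (adjusted p = 0.0254), and the length correction ended 5 calls and added that of histones (adjusted p = 0.0250). Of the lists called, 6 were called without each library in turn. Of 191 genes taken by the naming rule or shown for a family, 19 to 23 calls were lost without each library in turn, 22 with the block and 14 with DESeq2, and no called gene turned direction, while 4 LSM genes that were not called changed sign. The odds ratio of higher calls on chromosome IV ran from 1.86 to 2.25 and that of lower calls from 0.369 to 0.626 over all alternatives. On chromosome V the odds ratio of lower calls, 0.923 for all calls, reversed to 2.65 for calls of at least 2-fold, and the cause was not tested. For single-exon genes the odds ratio of higher calls passed the threshold with upper quartile scaling (0.593), library totals (0.559), no filter (0.435) and the deposited log2 values (0.617), and that of lower calls with no filter (0.509). With no filter, genes of few counts enter, and for the others the cause was not tested. In the simulation, which followed the trend of dispersion, genes of low level were recovered less often. There, 61.2% of 1.5-fold changes were recovered over all genes and 92.5% above 5 CPM.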

Other observations

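The tests of chromosome arms, of unequal shares between the mutant libraries and of extra copies on chromosome V, and the scan of gene families that share a name, were chosen after the results were seen. The scan covered 216 families with at least 8 tested genes, and camera called 24 of them (0 with an estimated correlation, all at adjusted p = 0.956). Mitochondrial ribosomal protein genes were lower, with 28 of 40 large-subunit genes (mrpl, median log2 fold change -0.23, adjusted p = 2.53e-05) and 18 of 29 small-subunit genes (mrps, median -0.23, adjusted p = 0.000642) called lower and 0 called higher. Those of the large subunit include mrpl-49, at -0.48 (SE 0.07), and those of the small subunit mrps-17, at -0.42 (SE 0.08). Transthyretin-related genes, a nematode family of small secreted proteins, had 29 of 50 lower and 2 higher (median -0.36, adjusted p = 3.77e-05), with ttr-44 falling from 73.6 ± 0.290 to 21.5 ± 1.51 CPM and ttr-49 from 15.5 ± 1.16 to 4.59 ± 0.197 CPM. Carboxylesterase genes had 15 of 32 lower and 4 higher (cest, adjusted p = 0.00697), with cest-8 falling from 7.54 to 2.13 CPM. Acyl-CoA dehydrogenase genes had 8 of 13 lower and 0 higher (acdh, adjusted p = 0.0195), with acdh-1 at -1.91 (SE 0.22). With the length correction these 5 families were still called (adjusted p from 0.000282 for mrpl to 0.0177 for acdh), with fewer genes lower in 3 of them: 16 of 40 for mrpl (median -0.16), 14 of 29 for mrps (-0.17) and 22 of 50 for transthyretin-related genes (-0.24).

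Families that were higher include amino acid transporter genes, with 6 of 9 higher and 1 lower (aat, median 0.56, adjusted p = 0.0179), led by aat-6, which rose from 6.52 ± 0.0829 to 19.2 ± 0.0782 CPM. The dod genes, named as downstream of DAF-16, had 5 of 8 higher and 1 lower (adjusted p = 0.0431). Levels of dod-19 rose from 159 ± 1.23 to 372 ± 9.16 CPM (log2 fold change 1.23, SE 0.06), and dod-3 fell from 108 ± 11.3 to 49.8 ± 4.18 CPM (-1.12, SE 0.08). Since dod-19 is also in the pathogen-response list and dod-3 in the list of DAF-16 targets, this family is not separate from those lists. Fatty acid elongase genes had 5 of 8 higher and 1 lower (elo, adjusted p = 0.0351), with elo-2 rising from 114 to 175 CPM, and cathepsin B-like genes had 5 of 8 higher and 1 lower (cpr, adjusted p = 0.0478), with cpr-3 at 1.17 (SE 0.09). With the length correction the elongase and cathepsin families were not called (adjusted p = 0.0523 and 0.0560), although their medians did not fall. They went from 0.50 (middle 50% of members 0.16 to 0.59) to 0.53 (0.18 to 0.64) and from 0.72 (0.09 to 0.94) to 0.76 (0.12 to 0.97). The median of all tested genes rose too, from -0.007 to 0.014, so relative to all genes these medians were kept. These lost calls thus do not show an effect of length. Without genes of chromosome IV, 3 of the 8 elongase genes were left, with a median of only 0.08 (-0.32 to 0.15). The higher level of the elongase family thus rests on its genes of chromosome IV, elo-2 among them. The cathepsin family kept its 8 genes, with a median of 0.74. Genes shown for a family were chosen after their values were seen, as the largest rises and falls.

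The 95% intervals given for the patterns below treat genes as independent, so they do not measure the spread between libraries. The first pattern is the rise of genes on chromosome IV. It was not removed by the length correction, after which the median on chromosome IV exceeded that of chromosomes I to III by 0.14 (bootstrap 95% interval 0.12 to 0.15), nor was it a feature of chromosome arms, since the 512 central genes of the chromosome exceeded the 1591 central genes of I to III by 0.18 (0.15 to 0.19). A candidate explanation is extra copies of chromosome IV in part of the mutant larvae, since the strain carries a translocation of IV and V. Non-green larvae were sorted, so larvae with such copies would have to lack the balancer's green marker or to have passed the sort. Such copies would shift the whole distribution, and the 25th percentile lay 0.12 higher than on I to III (0.09 to 0.13). Copies of the whole chromosome would raise its ends too. Its first and last blocks had medians of -0.09 and -0.01, within the range of the blocks of I to III (-0.11 to 0.06). These values argue against copies of the whole chromosome, while larvae with copies of the part between these blocks stay open. Unequal shares of such larvae in the mutant libraries cannot be told apart from other differences between single libraries. The excess of chromosome IV differed between the mutant libraries by 0.044 (0.038 to 0.052), but chromosome X differed by 0.042 (0.033 to 0.050) between the wild-type libraries, where no such copies are expected, and chromosome V by 0.033 (0.026 to 0.041) between the mutant libraries. A change of transcript levels along most of chromosome IV in the mutant would shift the 25th percentile too and stays open, untested.

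The second pattern is the fall of genes for the respiratory chain and of ribosomal protein genes. Short genes were lower in the mutant and also in mutant replicate 2 relative to mutant replicate 1 (medians from -0.07 in the shortest 20% to 0.04 in the longest 20%), a trend not seen between the wild-type libraries. The median of the ribosomal list, -0.15, lay within the central 95% of 10000 random lists matched on length and expression (-0.19 to -0.06), so the length trend may account for this fall. That of the respiratory chain list, -0.22, lay below the central 95% of its matched lists (-0.16 to -0.02), which argues against the length trend as its whole cause, and a lower level in the mutant stays open as a hypothesis. The matched genes could include members of other lists that fell. They were drawn independently of each other, so the ranges do not allow for genes that vary together.

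The third pattern is the concentration of changes of at least 2-fold on chromosome V, in both directions. Chromosome IV had an excess of rises of at least 2-fold only (odds ratio 1.91). Expression level did not account for the pattern on chromosome V, since the odds ratio over 10 strata of mean expression was 2.23 (95% interval 1.88 to 2.65). Nor did large families of named genes, since without families of at least 20 named genes the odds ratio was 2.95 (2.39 to 3.64). Genes without a locus name and smaller families stayed in, so the values cannot tell for them. Extra copies of a part of chromosome V do not explain the falls, since genes at least 2-fold lower were concentrated there too (odds ratio 2.65, 2.07 to 3.39). For the rises, the 10 nearest genes of at least 5 CPM were taken for each gene at least 2-fold higher. They had a median log2 fold change of 0.045 (-0.0052 to 0.092), against 0.5 or more expected from copies that span most of them. This argues against copies of such long stretches as the whole cause. The neighbours of 2 of the genes at least 2-fold higher reached 0.5, and for them such copies stay open. Shorter stretches would not move the median of 10 neighbours, so the values cannot tell for them. Copies of single genes and differences between the strains' sequences on chromosome V were not tested and stay open, as does the genotype itself.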
